A study of Homo sapiens with 4 samples.

How the data were processed

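The series holds 4 libraries of the MCF7 breast cancer line: 1 of the parental culture and 3 of subclones derived from single sorted cells, per the labels. Cells were captured with the 10x Chromium 3′ kit, per the labels' protocols. Cell Ranger 2.1.0 and the human assembly GRCh38 were used, per the submitters' processing notes, and the annotation release is not given in the sources used here. The deposited values are UMI counts per gene and cell, in 1 table of 20215 gene symbols and 14372 cells. They are whole numbers, every gene was seen in at least 3 cells, and totals ran from 4022 to 110401 UMIs per cell. The deposited table thus starts from barcodes already selected as cells, with a lowest total that differs between libraries (6176 UMIs in the parental library, 5553, 4083 and 4022 in WT3, WT4 and WT5).

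Each cell was assigned to a library by the end of its column name, which is the sample's title, and 0 columns were left without a library. Cells with at least 1000 UMIs and under 20% of UMIs from mitochondrial genes were kept. The first limit removed 0 cells and the second 105, 98, 170 and 110 cells of the parental library, WT3, WT4 and WT5. No doublet caller was run. A stricter filter (at least 3000 UMIs, under 10% mitochondrial, without the 5% of cells with the most UMIs in each library) served as an alternative that also removes likely doublets by depth. Cells were not clustered, since the samples are 1 cell line. Cell cycle phases were scored with scanpy 1.11.5 and used only to restrict an alternative to G1-called cells.

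Cells are not replicates, so UMIs were summed over the kept cells of each library and the library was the unit of the tests. CPM is the sum for a gene scaled to the library's total UMIs, without TMM. The main test was edgeR 4.0.16 (R 4.3.3) with TMM normalization, its filter on low counts by group and robust quasi-likelihood F-tests, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. With 1 library against 3 it has 2 residual degrees of freedom and assumes that the single library varies like the others. TMM factors were 1.04, 0.95, 1.02 and 0.98 for the parental library, WT3, WT4 and WT5. Gene lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry. On simulated counts with 200 changed genes, over 5 draws of 15672 tested genes, the edgeR test recovered 0% of 2-fold, 0% of 4-fold, 6% of 8-fold and 26.4% of 16-fold changes. Of 83 calls 2 were false, and 4.85% of unchanged genes had an unadjusted p under 0.05.

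After filtering, the libraries held 61320679, 55998817, 57475609 and 52816553 UMIs, which bounds counting error but not variation between cultures.

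Differences between subclones have 1 library on each side and no test. Ratios of CPM carry exact 95% intervals from the binomial share of the counts, which cover counting error only, and a floor of 3 counts per library stands in for a count of 0. A gene was counted with at least 100 UMIs in a library compared, a ratio of at least 2 and an interval that excludes 2. On subclones simulated with counting noise only, this rule found 100% of 200 genes changed 4-fold and 0 others among 11130 genes. The changed genes were drawn from those of at least 200 UMIs. The simulation therefore does not show how often the rule errs for genes near the minimum or with UMIs clustered in few cells.

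For measures per cell, each cell was thinned without replacement to 5322 UMIs, the 10th percentile of WT5, and 2799 cells were drawn per library. Distances used log1p of counts per 10000, 2000 variable genes and 20000 random pairs of cells per library. Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals. The variance of a gene was divided by its mean, which is 1 for pure counting noise, and lists were set against 10000 random lists matched on mean expression. These intervals and percentiles describe these libraries and do not replace replicates.

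Gene positions came from GENCODE release 29 on GRCh38, the build named in the processing notes. Of the 20215 symbols, 15973 matched that annotation, 48 of them at more than 1 position, and 92.2% of the genes over the count minimum had a position. Arms were split at approximate centromere positions written by hand, and log2 ratios used a pseudocount of 0.1 CPM. On subclones simulated with counting noise only and 8q raised 1.5-fold, the arm was found at 1.50-fold and 3 of 160 other combinations lay outside the range.

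Gene lists, the tests of the comparisons, the alternatives and the rule for named genes were fixed before the data were examined, apart from the alternatives named as added below and the tests of explanations named in the closing section as chosen later. Named genes were to be those passing the edgeR test with at least 20 CPM. Where fewer than 10 passed in a direction, genes of at least 20 CPM that differed at least 2-fold from every subclone were taken. For each subclone, up to 6 higher and 6 lower genes were ranked by the ratio to the nearer of the other 2, among genes of at least 200 UMIs in a library. Lists were described by members past the threshold, or else by their 3 most abundant members, and 12 hormone, keratin and cycle genes were named in any case. Clone-name genes were counted only.

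The alternatives were DESeq2 1.42.0 size factors in edgeR, library size alone, DESeq2's Wald test, limma-voom, other filters on genes and cells, thinned cells, no mitochondrial and ribosomal protein genes, G1-called cells, and leaving out each subclone in turn. For the other results they were other thresholds, numbers of variable genes, depths and scalings. Leaving out the cells that hold a UMI of a type I or III interferon gene was added after the data were seen, as was the G1 restriction for the lists. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.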

Results

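The data were single-cell RNA profiles of MCF7, an estrogen receptor-positive human breast cancer cell line, made with the droplet-based 10x Chromium 3′ method. There were 4 libraries: 1 of the parental culture and 3 of subclones, each grown from a single sorted cell (subclone replicates 1, 2 and 3, named WT3, WT4 and WT5 below as in the labels). The labels and title place the series in a study of how far strains of 1 cell line differ in their genomes and transcripts. After filtering, 2799 parental cells were kept, against 2891 in WT3, 3726 in WT4 and 4473 in WT5. Summed over these cells, the libraries held 61320679, 55998817, 57475609 and 52816553 unique molecular identifiers (UMIs), in the same order. The median cell held 19475 UMIs in the parental library, 17067 in WT3, 14586 in WT4 and 9682 in WT5. Each subclone was profiled in 1 library, so that a subclone and its library cannot be separated, and the p-values below rest on the spread between the 3 libraries that are compared with the single one. Markers of other lineages were close to absent: the summed markers of immune cells lay between 0.887 and 1.65 CPM (counts scaled to the library's total UMIs), those of endothelial cells between 0.107 and 0.212 CPM, those of fibroblasts between 1.59 and 2.04 CPM and the erythroid gene HBA1 between 1.77 and 2.99 CPM.

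The first comparison set the parental culture against its subclones. Among genes of at least 20 CPM, the one farthest above every subclone was KRT81, a hair-type keratin, at 905.5 CPM in the parental library against 36.1 ± 16.04 CPM in the subclones (SD, n = 3). Its log2 fold change was 4.58 (SE 0.48, edgeR adjusted p = 0.727). CALML5, a calmodulin-like protein of differentiating keratinocytes, stood at 252.0 CPM against 36.5 ± 11.9 CPM (log2 fold change 2.72, SE 0.34, adjusted p = 1.00). These 2 genes were the only ones of at least 20 CPM that were at least 2-fold higher in the parental library than in every subclone, and 4 were at least 2-fold lower. The lower ones were IFIT2, an interferon-induced gene, at 8.64 CPM against 26.4 ± 5.63 CPM, and APOE, an apolipoprotein, at 10.9 CPM against 36.6 ± 12.2 CPM. The others were OPTN, an autophagy receptor, at 8.27 CPM against 25.2 ± 7.40 CPM, and RPL22L1, a ribosomal protein paralog, at 337.4 CPM against 736.9 ± 49.9 CPM. None of these 6 genes passed the test. Without the cells holding an interferon UMI, IFIT2 was at 4.07 CPM against 7.46 in WT3, 16.8 in WT4 and 8.11 in WT5. It was then under 2-fold from WT3 and WT5, while its log2 ratio to the subclones' mean went only from -1.60 to -1.38. Below 20 CPM, ASCL1, a neuroendocrine transcription factor looked at after its values were seen, had a larger log2 fold change of 6.86 (SE 0.47, 10.5 CPM in the parental library against 0.083 ± 0.034 CPM, adjusted p = 0.0744).

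Across 16069 genes tested, edgeR called 0 at an adjusted p under 0.05, and 159 had an unadjusted p under 0.05. DESeq2's Wald test called 17 of the same genes, 4 higher and 13 lower in the parental library, and limma-voom called 0. ASCL1, KRT81, CALML5, IFIT2, APOE and RPL22L1 were among the 17, as were the interferons and chemokines IFNB1, IFNL2, IFNL3, CCL5, CXCL10 and CXCL11. Far fewer genes lay under an unadjusted p of 0.05 than chance alone gives, so the count is no sign of differences. In counts simulated with 1 library against 3, the edgeR test recovered 26.4% of 16-fold changes and 0% of 2-fold and 4-fold changes. Even there it could call only very large differences. Unchanged genes in the simulation fell under 0.05 about as often as chance gives. The simulation thus did not match the real p-values, and its recovery may not hold here.

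KRT81 lies on chromosome 12 from 52285913 to 52291534 on the minus strand (GRCh38, GENCODE release 29) and CALML5 on chromosome 10 from 5498697 to 5499555. IFIT2 lies on chromosome 10 from 89283694 to 89309276, OPTN on chromosome 10 from 13099449 to 13138308, APOE on chromosome 19 from 44905754 to 44909393 and RPL22L1 on chromosome 3 from 170864875 to 170870483. These are whole-gene spans, and the 3′ method counts molecules near the end of the transcript. KRT81 has close paralogs, KRT86 among them, from which its reads may not all be told apart, so its level carries that uncertainty. KRT86 had 989 UMIs in the parental library, where KRT81 had 55526. In WT3, WT4 and WT5 it had 758, 1601 and 450, against 1022, 2830 and 2163 for KRT81. The UMIs counted as KRT86 are thus too few to account for the KRT81 contrast. Other paralogs were not looked at.

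**Figure D1:**
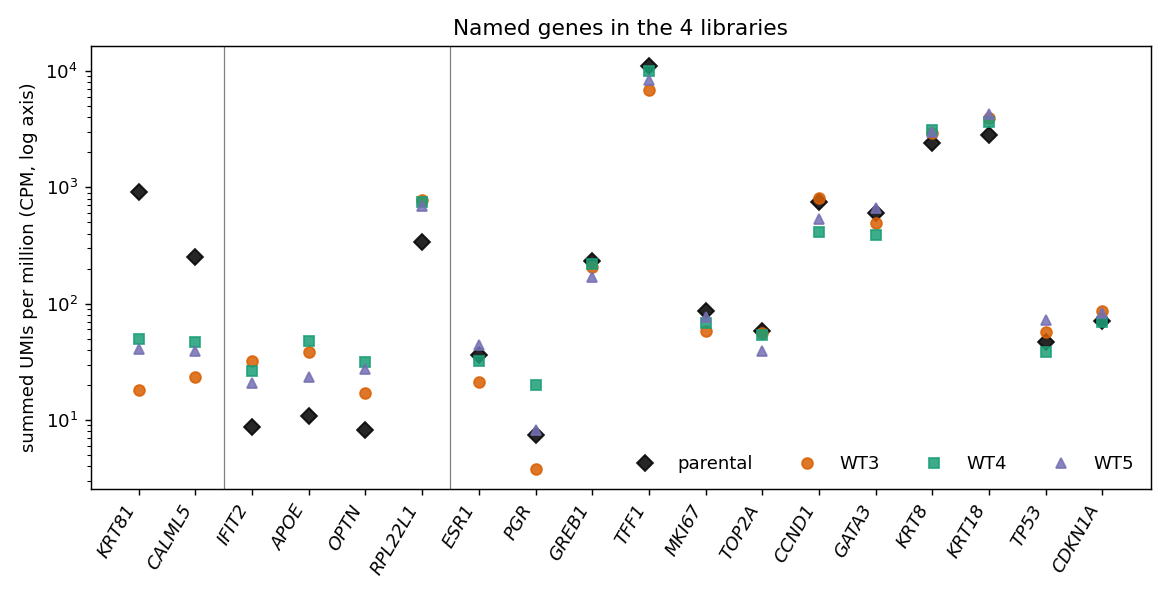
CPM (log axis) of the genes named by the fixed rule, 1 point per library (black diamond, parental; colored symbols, the 3 subclones); grey lines separate the genes higher in the parental library, those lower, and those named in any case. KRT81 and CALML5 lie far above the subclones in the parental library, at 905.5 and 252.0 CPM, while the hormone, keratin and cycle genes on the right lie close to or within the range of the subclones.

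After each cell was thinned to 5322 UMIs, 57.4% of parental cells held a KRT81 UMI (exact 95% binomial interval 55.5 to 59.2), against 2.07% (1.58 to 2.67) in WT3, 6.82% (5.92 to 7.82) in WT4 and 5.57% (4.75 to 6.49) in WT5. Without thinning the shares were 76.7%, 5.22%, 10.7% and 9.08%. CALML5 was found in 42.9% (41.1 to 44.8) of thinned parental cells and in 4.97%, 11.4% and 14.6% of those of WT3, WT4 and WT5. The subclone shares bound the background from free RNA in the subclone libraries only, and the intervals cover counting error only.

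Luminal and hormone-response genes showed no common direction between the parental culture and its subclones, though single genes lay outside the subclones' range. ESR1, the estrogen receptor, was at 36.2 CPM in the parental library against 32.5 ± 11.2 CPM in the subclones, and its target TFF1 at 10980.1 CPM against 8348.1 ± 1548.0 CPM. GREB1 was at 231.6 CPM against 198.2 ± 27.2 CPM, and PGR, the progesterone receptor, at 7.49 CPM against 10.6 ± 8.32 CPM. TFF1 and GREB1 were higher in the parental library than in each subclone. The luminal keratins KRT8 (2377.6 against 3008.6 ± 81.7 CPM) and KRT18 (2834.4 against 3920.9 ± 303.7 CPM) were lower in the parental library than in each subclone, and neither passed the test. GATA3 (599.2 against 515.3 ± 133.9 CPM), CCND1 (743.8 against 584.7 ± 198.0 CPM), TP53 (46.8 against 55.8 ± 17.2 CPM) and CDKN1A (71.6 against 79.4 ± 9.004 CPM) lay within the subclones' range or close to it. The estrogen-induced list (47 measured members, median log2 fold change -0.01, camera adjusted p = 0.978) and the luminal list (22 members, median 0.10, adjusted p = 0.978) did not stand apart. Without WT3 the luminal median was -0.04 and without WT4 -0.10, and the estrogen-induced median was 0.01 without WT4 and 0.05 without WT5. With library size alone the luminal median was 0.18 and the estrogen-induced median 0.07. The mean of the estrogen-induced list was -0.17 although its test pointed up, and the mean of the luminal list was -0.02. Of the 47 estrogen-induced members, 11 were highest and 10 lowest in the parental library, so its median near 0 covers members that went both ways.

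Among 21 gene lists, the S phase list was higher as a group in the parental library. Of its 43 measured members, 33 had their highest value of the 4 libraries there, at a median log2 fold change of 0.27 (camera adjusted p = 1.8e-09, and adjusted p = 0.388 with an estimated correlation). Its most abundant members were GINS2, a replication factor, at 144.5 CPM against 108.1 ± 7.502 CPM, RRM2, a subunit of ribonucleotide reductase, at 105.7 against 65.2 ± 9.35 CPM, and PCNA at 64.8 against 54.7 ± 10.9 CPM. The G2/M list had 29 of 54 members highest in the parental library (median 0.11, adjusted p = 0.0289, and adjusted p = 0.391 with an estimated correlation; adjusted p = 0.0652 without WT3 and 0.212 without WT5), among them HN1 at 684.2 against 611.3 ± 110.4 CPM and CKS1B at 356.4 against 315.5 ± 5.60 CPM. With library size alone the median was 0.36 for the S phase list and 0.19 for the G2/M list. No member of either list passed the test over all genes, and none did when adjusted over the list alone.

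Antigen presentation genes were lower as a group in the parental library, and interferon genes were lower in the parental library and in WT5. Of 18 members of the MHC class I list, 11 had their lowest value there (median log2 fold change -0.73, camera adjusted p = 4.8e-11, and adjusted p = 0.423 with an estimated correlation). Without WT4 that median was -0.39. B2M, the light chain of MHC class I, was at 433.8 CPM against 762.4 ± 257.0 CPM, PSME2 at 305.2 against 352.3 ± 72.9 CPM and PSME1 at 198.3 against 303.9 ± 94.1 CPM. Of 43 interferon-response members, 17 were lowest in the parental library (median -0.44, adjusted p = 1.9e-14, and adjusted p = 0.501 with an estimated correlation). WT5 was as low: the mean log2(CPM + 1) of the list was 5.33 in the parental library, 5.34 in WT5, 5.70 in WT3 and 6.08 in WT4. IFI27 was at 4540.5 CPM against 8601.9 ± 2548.3 CPM, whereas ISG15 at 4835.0 against 3651.3 ± 486.0 CPM and LY6E at 1953.4 against 1601.7 ± 1051.3 CPM were above the subclones' mean. Both lists were highest in WT4, where the MHC class I median was 0.58 in the comparison of WT4 with the other 3 libraries.

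Other lists with lower values in the parental library were drug transporters and detoxification (21 members, median -0.71, adjusted p = 1.7e-09, and adjusted p = 0.388 with an estimated correlation) and the ATF4 amino acid response (28 members, median -0.35, adjusted p = 1.6e-06, and adjusted p = 0.388 with an estimated correlation). Without WT3 the ATF4 median was -0.16. The parental library was lowest for 7 of the 21 drug transporter members, 10 of the 28 ATF4 members and 7 of 15 NF-kB targets. For drug transporters WT3 was close to it, with a mean log2(CPM + 1) of 3.15 against 3.03. The median difference in log2(CPM + 1) from the mean of the other libraries was smaller than the median fold change. It was -0.31 for drug transporters, -0.21 for ATF4 and -0.37 for NF-kB targets. GSTM3, a glutathione transferase, was at 271.1 CPM against 458.8 ± 41.0 CPM and NQO1, a quinone reductase, at 189.7 against 322.9 ± 128.5 CPM. The amino acid transporter subunits SLC7A5 and SLC3A2 were at 116.8 against 175.1 ± 45.7 CPM and 90.3 against 141.0 ± 3.54 CPM. NF-kB targets (15 members, median -0.76, adjusted p = 5.0e-06, and adjusted p = 0.388 with an estimated correlation) included NFKBIA at 41.8 against 69.2 ± 3.23 CPM. Nuclear genes of oxidative phosphorylation (57 members, median -0.15, adjusted p = 5.0e-04), ribosomal proteins (78, -0.11, 0.00745), proteasome subunits (31, -0.16, 0.0232), hypoxia and glycolysis (28, -0.22, 0.0363) and cholesterol synthesis (25, -0.19, 0.0363) moved by less. The parental library was not the lowest of the 4 for most of these lists: by mean log2(CPM + 1), WT3 was lower for oxidative phosphorylation (8.17 against 8.25), the proteasome (6.67 against 6.83) and cholesterol (4.79 against 4.95), and WT4 for hypoxia (4.95 against 4.998) and ribosomal proteins (11.400 against 11.445). With an estimated correlation their adjusted p ran from 0.568 for oxidative phosphorylation and for hypoxia to 0.749 for ribosomal proteins and cholesterol synthesis and 0.785 for the proteasome. Their medians depended on single subclones: without WT5 they were -0.08 for oxidative phosphorylation, -0.09 for the proteasome, -0.06 for hypoxia and 0.03 for cholesterol, and without WT3 -0.03 for ribosomal proteins and -0.32 for cholesterol (-0.12 without WT4). They depended on the scaling too: with library size alone they were -0.07 for oxidative phosphorylation, -0.08 for the proteasome, -0.03 for ribosomal proteins, -0.13 for hypoxia and -0.11 for cholesterol, and the last 4 of these lists did not pass. In all, 12 lists passed with the preset correlation and 0 with an estimated correlation or with fry.

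The remaining lists did not pass. They were basal and mesenchymal genes (19 members, median -0.17, adjusted p = 0.506), the unfolded protein response (20, 0.01, 0.849), p53 targets (30, -0.12, 0.488), mitochondrially encoded genes (13, -0.02, 0.656), immediate early and heat shock genes (25, -0.14, 0.274), MYC-regulated growth (30, -0.08, 0.696) and genes of segments amplified in MCF7 (33, 0.09, 0.173). Leaving out 1 subclone moved each of these medians by over 1.5 times or turned its sign. The basal median was 0.23 without WT3 and -0.43 without WT5, and that of the amplified segments 0.22 without WT3 and -0.0034 without WT4. Without WT3, p53 targets were at -0.02, immediate early genes at -0.02 (-0.23 without WT4 and -0.05 without WT5), MYC-regulated growth at -0.0056 (-0.04 without WT5), the unfolded protein response at -0.04 (0.15 without WT5) and mitochondrially encoded genes at 0.10 (0.02 without WT4 and -0.13 without WT5). The scaling mattered too. With library size alone the medians were 0.06 for mitochondrially encoded genes, 0.0079 for MYC-regulated growth, -0.06 for basal genes and -0.04 for p53 targets. They were -0.05 for immediate early genes, 0.17 for the amplified segments and 0.09 for the unfolded protein response. In G1-called cells the p53 median was 0.07. Metallothioneins had too few measured members for a test and summed to 993.1 CPM in the parental library against 775.1 in WT3, 1087 in WT4 and 1469 in WT5.

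The same fit was then run with each subclone as the single library against the other 3. It called 0 genes for WT3, WT4 and WT5 alike, with 725, 1402 and 1271 genes at an unadjusted p under 0.05, against 159 for the parental library. The parental count was 281 without WT3, 173 without WT4 and 327 without WT5. DESeq2 called 75, 267 and 156 genes, and limma-voom called 0 for each. Such counts depend on the spread among the other 3 libraries as well as on distance, so they do not measure distance alone. The coefficient of variation from edgeR's common dispersion was 0.346 with the parental library single. It was 0.303, 0.283 and 0.295 with WT3, WT4 and WT5 single. Over genes of at least 20 CPM the root mean square log2 fold change was 0.29 for the parental library, 0.37 for WT3, 0.41 for WT4 and 0.40 for WT5. Several lists passed in more than 1 subclone, and none passed with an estimated correlation. Each subclone is among the 3 libraries set against the others, so a list low in 1 of them pushes the others up, and opposite directions are no separate findings. Differences between subclones in these lists were not tested. Immediate early and heat shock genes passed in all 3 (camera adjusted p = 0.00985 and higher in WT3, 5.0e-05 and lower in WT4, 0.0465 and higher in WT5), with adjusted p = 0.890, 0.952 and 0.731 with an estimated correlation. Genes of amplified segments were higher in WT3 (adjusted p = 3.3e-04) and lower in WT4 (1.3e-04), with adjusted p = 0.890 and 0.952 with an estimated correlation. In WT3 the basal and mesenchymal list was higher (median 0.68, camera adjusted p = 1.1e-04, and adjusted p = 0.807 with an estimated correlation), and in WT5 it was lower (median -0.77, adjusted p = 7.6e-04, and adjusted p = 0.513 with an estimated correlation). In WT4 the interferon list was higher (median 0.58, adjusted p = 1.2e-12, and adjusted p = 0.952 with an estimated correlation), and in WT5 it was lower (median -0.44, adjusted p = 0.00291, and adjusted p = 0.766 with an estimated correlation).

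The parental profile lay between those of the subclones. Over 4365 genes of at least 20 CPM, the root mean square difference in log2(CPM + 1) to the parental library was 0.36 for WT3, 0.43 for WT4 and 0.39 for WT5. Between subclones it was 0.48 for WT3 and WT4, 0.49 for WT3 and WT5 and 0.48 for WT4 and WT5. The parental library held the highest or lowest of the 4 values for 34.3% of these genes, whereas WT3 did for 52.5%, WT4 for 55.8% and WT5 for 57.5%. With 4 equivalent libraries each would do so for 50%. The 4 are not equivalent by design, since each subclone was grown from a single cell of the parental culture. The 50% is therefore no expectation for the parental library.

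**Figure D2:**
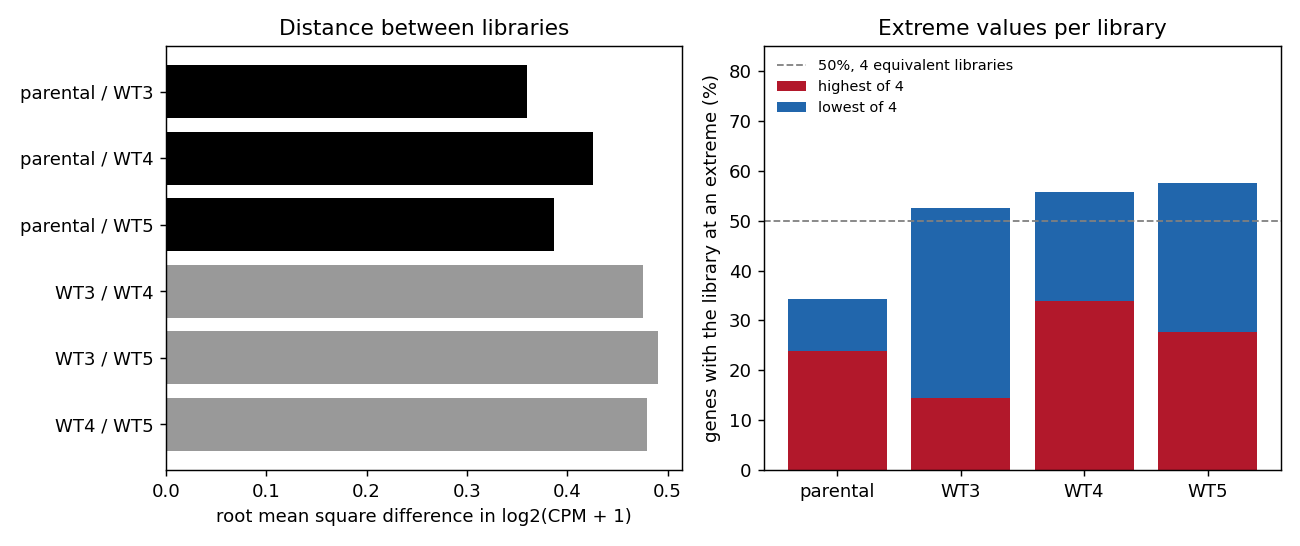
Left, root mean square difference in log2(CPM + 1) over 4365 genes for each pair of libraries (black, pairs with the parental library; grey, pairs of subclones). Right, percent of these genes with each library at the highest or lowest of the 4 values, with a dashed line at 50%; the parental library is at 34.3% and the subclones are between 52.5% and 57.5%.

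The next comparison asked which genes separate the subclones from one another, as a description with 1 library each. Of 11798 genes with at least 100 UMIs in a subclone, 1313 differed at least 2-fold between some pair of subclones with a 95% counting interval that excluded 2. There were 629 between WT3 and WT4, 664 between WT3 and WT5 and 728 between WT4 and WT5. By the same rule 297, 493 and 330 genes separated the parental library from WT3, WT4 and WT5. WT3 was higher than both other subclones for 157 genes and lower for 84, WT4 for 136 and 96, and WT5 for 134 and 101. With TMM scaling these numbers were 169 and 75, 111 and 109, and 134 and 97, so that the balance of WT4 depends on the scaling. These differences have no replicate check.

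The largest ratios in WT3 belonged to genes of varied function. CYP24A1, the vitamin D 24-hydroxylase, was at 23.6 CPM in WT3 against 0.0696 in WT4 and 0.0947 in WT5, 249.6 times the nearer one (95% counting interval 106.7 to 769.9). DIO2, a deiodinase, was 36.3 times higher (20.5 to 70.7), S100A7, a keratinocyte calcium-binding protein, 31.2 times (18.7 to 56.1), and ACTG2, smooth muscle actin, 29.8 times (22.7 to 39.7). KRT17, a basal keratin, stood at 74.0 CPM in WT3 against 3.08 and 2.71 CPM, and SPRR1B, of the cornified envelope, at 3.11 CPM against 1 UMI in WT4 and 0 in WT5, though it was at 11.6 CPM in the parental library. Lower in WT3 were NOVA1, a splicing factor, at 0.375 CPM against 19.7 in WT4 and 15.9 in WT5, DNASE1L2 at 0.768 against 17.3 and 14.7, and the long noncoding RNA LINC01138 at 0.286 against 14.998 and 8.50. NAALADL2 (16.8 times lower than the nearer subclone), SEMA3E (12.99 times) and ZNF385B (10.9 times) were also lower.

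Several of the largest ratios in WT4 belonged to transcripts close to absent on 1 side, which ranking by ratio favors in every subclone. CA4, a carbonic anhydrase, had 0 UMIs in WT4 and 391 and 495 in WT3 and WT5, which makes it at least 133.8-fold lower against a floor of 3 counts in the library (lower 95% counting limit 108.3). TIMP3, an inhibitor of metalloproteinases, was 13.1 times lower than in the nearer subclone (9.58 to 18.4), GJA1, a gap junction protein, 9.92 times (7.54 to 13.3), DCLK1 13.3 times (6.98 to 28.4), C16orf45 10.7 times and BARX2 8.59 times. Higher in WT4 were DNALI1, a dynein light chain, at 18.3 CPM against 0.768 and 0.284, TCN1, a vitamin B12 carrier, at 7.01 against 0.143 and 0.227, and HOXB6, a homeobox gene, at 5.85 against 0.25 and 0.284. TEX101 had 281 UMIs against 1 in WT3 and 0 in WT5, CRCT1 203 against 5 and 0, and the noncoding MIR548XHG 260 against 0 in both, at least 79.6-fold higher against the same floor (lower counting limit 68.2), with 149 in the parental library.

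In WT5, GPC5, a glypican, had 314 UMIs against 0 in both other subclones, at least 111.0-fold higher against a floor of 3 counts in the library (lower 95% counting limit 89.7), and 1 UMI in the parental library. STC1, a secreted stanniocalcin, was 13.5 times higher than in the nearer subclone (10.1 to 18.5), TNFRSF11B, osteoprotegerin, 9.61 times (7.41 to 12.6), FAM110B 15.6 times (10.3 to 24.7) and PLCXD3 8.15 times (5.77 to 11.8). ZCCHC11 was at 2.84 CPM against 0.0179 and 0.0522, and at 3.54 CPM in the parental library. Lower in WT5 were MYLK, myosin light chain kinase, at 0.417 CPM against 13.4 in WT3 and 10.2 in WT4, and PSG9, HMCN1, FERMT1 and APOD, which were 18.7, 14.3, 14.01 and 10.2 times lower than in the nearer subclone. STXBP6 had 2 UMIs in WT5 against 60 and 476. PSG9 belongs to a family of near-identical genes and its count is uncertain for that reason.

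Genes also differed in shares of cells. In cells thinned to 5322 UMIs, MGP, a matrix protein, was found in 21.8% of parental cells, 12.8% in WT3, 63.2% in WT4 and 76.7% in WT5. COL12A1, a collagen, was found in 12.4% (11.2 to 13.7) of WT4 cells against 0.179% in WT3, 2.97% in WT5 and 1.54% in the parental library. KRT17 was found in 7.72% (6.76 to 8.77) of WT3 cells against 0.393% in WT4, 0.572% in WT5 and 3.04% in the parental library. MGP and COL12A1 were chosen after their values were seen.

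**Figure D3:**
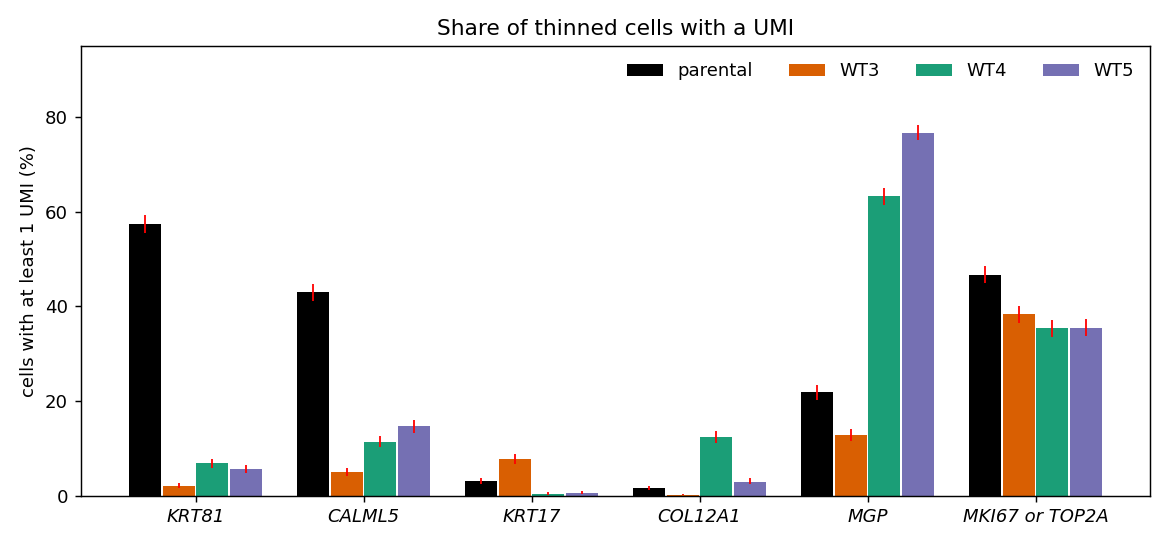
Percent of cells with at least 1 UMI of a gene after thinning to 5322 UMIs, 2799 cells per library (black, parental; colors, subclones; red bars, exact 95% binomial intervals for counting error). KRT81 and CALML5 lead in the parental library at 57.4% and 42.9%, MGP in WT5 at 76.7%, and the share with MKI67 or TOP2A is 46.7% in the parental library against 35.3% to 38.3% in the subclones.

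Cells with MKI67 or TOP2A were more frequent in the parental library. Of thinned cells, 46.7% (44.8 to 48.6) held a UMI of MKI67 or TOP2A there, against 38.3% (36.5 to 40.2) in WT3, 35.3% (33.6 to 37.1) in WT4 and 35.5% (33.7 to 37.3) in WT5. Without thinning the shares were 71.5%, 62.6%, 50.5% and 48.4%, which also carry the difference in UMIs per cell. The summed level of MKI67 was 86.3 CPM in the parental library against 67.5 ± 9.48 CPM (SD, n = 3), and that of TOP2A was 58.0 against 49.7 ± 9.22 CPM. Of the single genes looked at in thinned cells, only MKI67 had an interval clear of every subclone. It was found in 35.0% (33.2 to 36.8) of parental cells against 28.2% (26.5 to 29.9) in WT5, the nearest. TOP2A was at 23.4% (21.9 to 25.1) against 22.3% (20.7 to 23.8) in WT3. PCNA was at 26.7% against 25.9% in WT5, and MCM5 at 8.07% against 7.18%. Not every cycling gene had this order: CDK1 was found in 11.3% of parental cells and 12.6% of WT5 cells, and CCNB1 in 19.2% and 20.2%. Thinning left out 0 cells of the parental library and WT3, 181 of WT4 and 447 of WT5 for having too few UMIs.

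Cells of the parental library were slightly farther from one another than cells of a subclone. The mean distance between random pairs of thinned cells over 2000 variable genes was 26.57 in the parental library, 26.07 in WT3, 26.25 in WT4 and 26.18 in WT5, a ratio of 1.015 to the subclones' mean of 26.17 ± 0.09 (SD, n = 3). Without the cell cycle lists the ratio was 1.013. An exact permutation test of 1 library against 3 cannot give a p under 0.25. With 500 variable genes the parental library was no longer the highest, with a distance of 14.73 against 14.89 in WT3.

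Genes that separate the subclones were also unusually variable within each library. For the 465 of these genes measured in parental cells, the median log2 ratio of variance to mean was 0.16, against 0.06 in random lists of the same expression. The excess was 0.108 in the parental library, 0.101 in WT3, 0.10 in WT4 and 0.078 in WT5. In each of the 4 libraries the list stood at percentile 100 of 10000 random lists. The list was taken from these same libraries by a rule that covers counting error only. Genes whose UMIs cluster in few cells pass such a rule more easily, so part of the excess can be built in. The parental excess was 0.015 above the subclones' mean, with an SD of 0.013 between subclones, and at a 1.5-fold threshold the difference was 0.0011.

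Expression also differed by chromosome arm. Over 41 arms in each of 3 subclones, 64 combinations of arm and subclone had a median log2 ratio, against the mean of the other 2 subclones, outside the central range of matched random lists, where chance gives 1.23. They fell on 27 arms. Each subclone is part of the reference of the other 2, so 1 shifted arm pushes the others to the opposite side and the combinations are not separate findings. In WT4 the 190 measured genes of 17p, the arm of TP53, had a median of -0.51 and those of 5p a median of -0.41, whereas 2q was at 0.32 and 3q at 0.33. In WT5, 2p (-0.40), 2q (-0.42), 3q (-0.45) and 21q (-0.34) were lower, and 16p (0.38), 9q (0.33), 10q (0.31) and 1p (0.29) were higher. In WT3, 13q (-0.38), 10p (-0.37) and 7p (-0.31) were lower and 19p (0.23) was higher. These are raw medians, and the random lists of WT3 themselves lay below 0. Taken from the random median, the largest shift in WT3 was that of 19p at 0.32, against -0.30 for 13q, -0.28 for 10p and -0.23 for 7p. Those of 17p, 19q and 11q were 0.23, 0.22 and 0.21. In all, 10 arms of WT3 lay above the range and 11 below it. Some of these shifts lay mainly in the first part of the arm, split at its middle gene. Measured from the random median, the parts were at -0.44 and -0.10 for 13q and -0.35 and -0.10 for 7p in WT3. For 21q in WT5 they were at -0.46 and -0.02. TP53 itself was at 38.1 CPM in WT4, 57.0 in WT3 and 72.4 in WT5. Against the mean of the 3 subclones, 25 of 41 arms of the parental library lay outside the range, with shifts from the random median between -0.18 for 6q and 0.17 for 1p. After trends with gene density and expression were removed, 21 of these remained outside, and 8q, 17p, 17q and 19p did not.

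**Figure D4:**
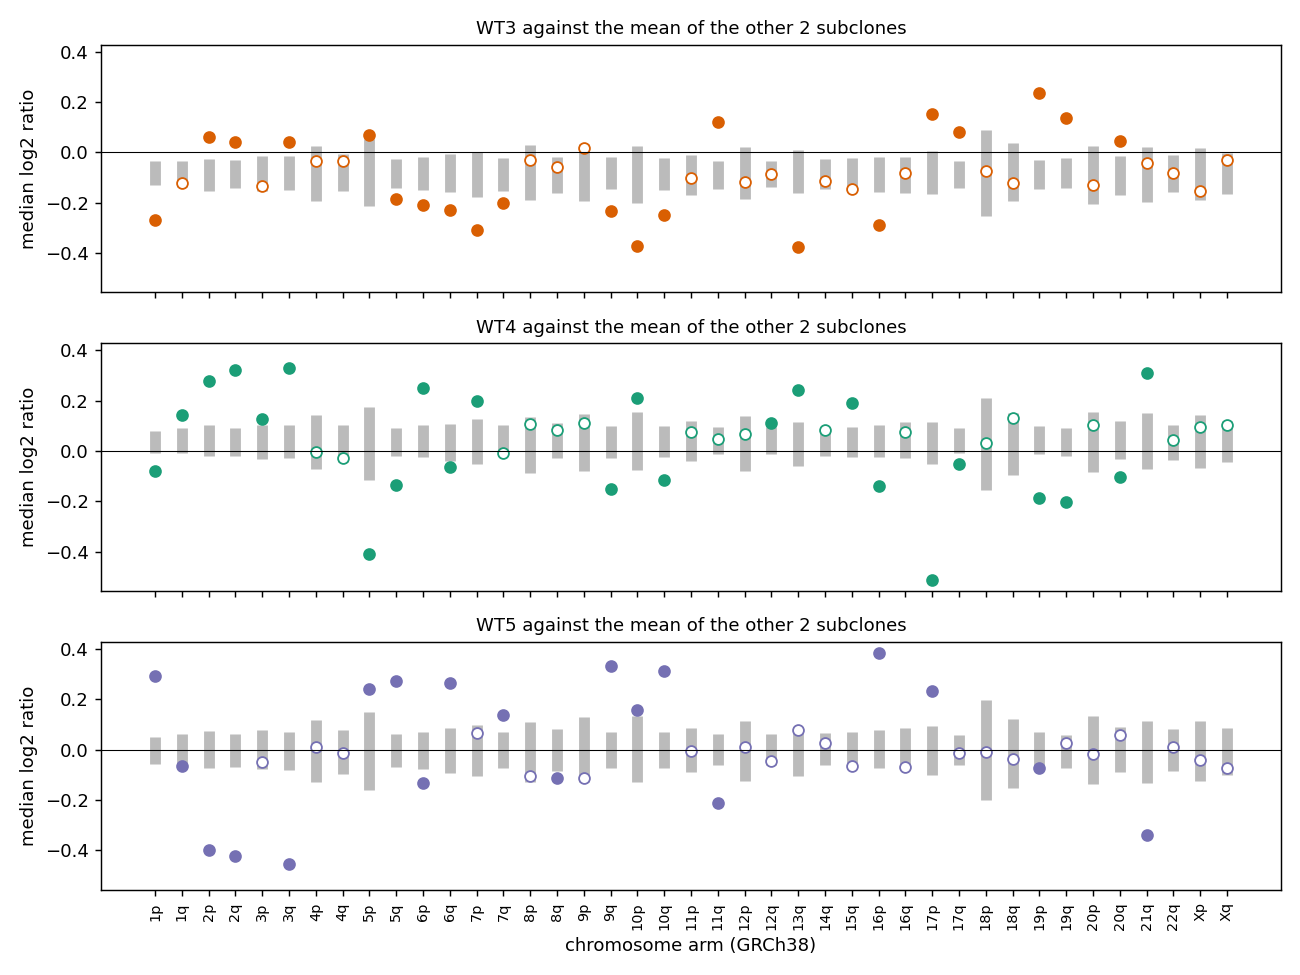
Median log2 ratio of CPM of each subclone to the mean of the other 2, per chromosome arm with at least 30 measured genes (filled points, outside the range of 10000 random gene lists matched on expression, drawn as grey bars that leave out 0.5% at each end; open points, within it). WT4 reaches -0.51 on 17p, and WT5 lies between -0.40 and -0.45 on 2p, 2q and 3q.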

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

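The only alternatives chosen after the data were seen were leaving out interferon-positive cells and, for the lists, the restriction to G1-called cells. The parental comparison called 0 genes in edgeR, 17 with DESeq2's Wald test, and 1, ASCL1, both without the low-count filter and in G1-called cells. Leaving out each subclone in turn gave 0 to 0. Summed over the 3 subclones as single libraries, the count was 0, and it was 498 with DESeq2, 3 with library size alone (CA4, TEX101 and HOXB6 in WT4), 2 without the low-count filter, 5 in thinned cells and 1 in G1-called cells (CA4 in WT4). The cause of these gains was not tested. Other alternatives left both counts at 0.

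Of 21 lists 12 passed, and the number was 0 with an estimated correlation, 0 with fry, 7 in G1-called cells, 8 with library size alone (without hypoxia, 0.0652, ribosomal, 0.0652, cholesterol, 0.0735, and proteasome, 0.0735) and 12 without interferon-positive cells. Leaving out a subclone gave 7 to 11, the lowest without WT5, when the G2/M, cholesterol, hypoxia, oxidative phosphorylation and proteasome lists no longer passed (adjusted p from 0.212 to 0.657). Without WT3 the G2/M (0.0652), hypoxia (0.0634) and ribosomal (0.523) lists were lost and the amplified segments gained (2.3e-04, median 0.22). Without WT4 cholesterol (0.0732) and proteasome (0.0741) were lost, and immediate early and heat shock genes gained (5.2e-04). G1-called cells lack cycling cells by construction, where the S phase list no longer passed (adjusted p = 0.182) and the G2/M list turned downward (adjusted p = 0.574). There hypoxia (0.0738), cholesterol (0.0532) and ribosomal proteins (0.659) were lost as well, and the ATF4 median went from -0.35 to -0.17. Among named genes, 4 without a call changed sign: ESR1 without WT3 (-0.12, and 0.36 without WT5), PGR in G1-called cells (0.017) and without WT4 (0.23, and -0.94 without WT3), GATA3 without WT4 (-0.048, and 0.35 without WT5) and CDKN1A in G1-called cells (0.13). Another 259 values kept their sign uncalled, and 5 were called, all with DESeq2's Wald test. Of the ratios of genes named for a subclone, 98 values stayed within their counting interval and 10 moved, all in G1-called cells, where fewer cells also lower the bounds of genes with 0 counts elsewhere (CA4 75.2, GPC5 44.3).

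The 1313 genes that separate subclones became 3372 at 1.5-fold and 561 at 3-fold, by the construction of the rule, and stayed between 888 and 1721 under the other settings. The distance ratio of 1.015 moved to 1.008 with 500 variable genes, 1.020 with 5000 and 1.043 with 1 minus the correlation. The difference in variance excess of 0.015 was 0.0011 at 1.5-fold. The cycling-marker ratio (1.28 to 1.33) and the count of shifted arms (64 to 65) held.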

Other observations

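Both tests of the KRT81 pattern, the test of arm parts and the covariation within subclones were chosen only after the result was seen. So was the removal of interferon-positive cells, whose 2 expectations were set aside once their values were known and are given here as plain values. How the chance sampling of KRT81 is judged was also changed after its value was seen, because it depends on which share of cells is used. The other tests were written before the result they measure.

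Interferon and chemokine transcripts came from a few cells. A UMI of IFNB1, IFNL1, IFNL2 or IFNL3 was present in 10 of 2799 parental cells (0.357%, exact 95% interval 0.172 to 0.656), 42 of 2891 in WT3 (1.45%, 1.05 to 1.96), 21 of 3726 in WT4 (0.564%, 0.349 to 0.860) and 40 of 4473 in WT5 (0.894%, 0.640 to 1.22). The highest single cell held 11 such UMIs in the parental library, 363 in WT3, 137 in WT4 and 636 in WT5. The 10 highest cells carried 90.2% of all UMIs of the chemokine CCL5 in WT3, 74.2% in WT4 and 92.7% in WT5. Without interferon-positive cells the median log2 ratio of parental to subclones over CCL5, CXCL10 and CXCL11 went from -4.13 to -0.97. The latter value is that of CXCL11, which had 0 UMIs in the parental library, so its size is set by the pseudocount. CCL5, the most abundant, went from -4.13 to -2.92 and stayed at 0.54 CPM in the parental library against 4.51 in WT3, 3.87 in WT4 and 5.83 in WT5. Over 60 other interferon and MHC class I genes it went from -0.37 to -0.34, and IFI27 stayed at -0.92. IFIT2, named in the parental comparison, went from -1.60 to -1.38. It was then at 4.07 CPM in the parental library against 7.46 in WT3, 16.8 in WT4 and 8.11 in WT5, so it no longer met the 2-fold rule against WT3 and WT5.

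ASCL1 was found in 149 of 2799 parental cells (5.32%, exact 95% interval 4.52 to 6.22) and in 1, 6 and 2 cells of WT3, WT4 and WT5. Its level was 10.5 CPM against 0.071, 0.122 and 0.057 CPM. It is below the 20 CPM minimum for named genes and was singled out after its values were seen.

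Many chromosome arms stood apart as a whole between subclones. A bias that follows gene density or expression level does not explain this: after both trends were removed, 96.9% of the combinations of arm and subclone remained outside the range on the same side. Different copy numbers of whole arms cannot be told apart from other causes. With the subclone of each arm chosen by the first part of its genes, the other part lay to the same side in 88.9% of 27 arms. With the second part choosing, it did so in 78.3% of 23 arms, where chance gives 50%. The other part was itself outside the random range on that side in 18 of these 27 arms and in 18 of these 23. GC content and copy number itself were not measured, and some shifts start within an arm, such as 20q in WT4 (0.06 and -0.57 in its 2 parts) and 11q in WT5 (0.03 and -0.53).

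The parental library lay between the subclones for most genes, and its greater depth is not the reason: in thinned cells it was at an extreme for 36.4% of genes. A mixture of cells with fixed subclone-like profiles could give this. In parental cells, genes higher and genes lower in a subclone had correlations below the 1st percentile of random pairs for 3 of 3 subclones. The correlations were -0.18 for WT3, -0.10 for WT4 and -0.03 for WT5, against random medians of 0.11, 0.12 and 0.14. However, covariation of these genes within single subclones too gave values below the 1st percentile in 9 of 9 combinations. Genes of the cell cycle lists were left out of the subclone lists but not of the random pairs. The pairs were matched on mean expression only, so the percentiles cannot weigh either explanation and both remain open. For each of the 3 lists the parental library had the lowest correlation of the 4. The descent of the subclones from the parental culture was not weighed as a cause.

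KRT81 was high in the parental library and low in all 3 subclones. A few parental cells with free RNA in the rest cannot account for it: the 653 parental cells without a UMI limit free RNA to a mean of 1.82 UMIs per cell, which would put 0.173% of cells at 10 UMIs or more, and 35.7% were there, 35.5 percentage points above that expectation. Chance sampling of 3 founder cells with a fixed KRT81 state cannot be told apart from other causes. The probability that 3 random parental cells all lack a KRT81 UMI was 0.0774 in thinned and 0.0127 in unthinned cells, and 0.156 if at least 5 UMIs are asked for. The 10 highest cells carried 65.3% of KRT81 UMIs in WT3, 31.6% in WT4 and 43.3% in WT5. A UMI was found in 151, 399 and 406 cells of these subclones, and at least 10 UMIs in 19, 68 and 38. The origin of such cells was not examined, so they cannot decide whether the state stays fixed in all descendants of a founder. They do not argue against chance sampling of founders.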
